A study of Homo sapiens with 2 samples.

How the data were processed

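RNA sequencing was analysed from 2 libraries of NCI-H460 cells, a human large cell lung carcinoma line. The sample labels and the series title name NCI-H460, whereas the design text names NCI-H469, and the sample labels were followed. The control library is labelled siControl, and the other came from cells given an siRNA against CYP4F11. Cells were transfected with a lipid reagent and collected 24 h later, per the labels. The treatment label of the control says that it received no siRNA against CYP4F11 and does not name a control sequence, and the sequence of the CYP4F11 siRNA was not given in the sources used here. Per the labels' protocols, poly-A RNA was selected and made into strand-specific libraries by the dUTP method. The labels place both libraries in the same batch. There was 1 library per group, so neither group had a replicate.

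The authors deposited 1 table with a whole-number read count per gene for both libraries, not normalised, and with the length of each gene model in bases, which was not used for any value. The submitters' processing notes name fastp, HISAT2 2.2.1, featureCounts 2.0.6, edgeR 4.0.16 and the build GRCh38. The role of each tool, its parameters and the strand setting of the counting were not given in the sources used here. Because the strand setting is unknown, counts of overlapping and antisense genes may hold each other's reads. The 58735 gene identifiers, their coordinates and their symbols were all identical to those of GENCODE release 29, which supplied transcript sequences and exon positions on GRCh38. The number of further sample columns in the table was 0.

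The counts summed to 16207785 in the siControl library and 13002179 in the siCYP4F11 library. A floor of 3 counts corresponded to 0.185 CPM (counts scaled to a common library size) in the siControl library and 0.231 CPM in the siCYP4F11 library. Effective library sizes were computed from the deposited counts by the TMM method in edgeR 4.0.16 under R 4.3.3, with factors of 0.996 and 1.004. For each gene the log2 ratio of siCYP4F11 over siControl was taken after 0.5 was added to each count. Its 95% interval came from the exact Clopper-Pearson interval of the siCYP4F11 share of the 2 counts. All intervals of single genes cover counting error only, since reads without molecular identifiers are not independent molecules and no replicate spread exists. No p-value was computed, and edgeR's quasi-likelihood test was not run because it needs replicates. Every value compares these 2 libraries and not the conditions in general.

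Genes with a mean CPM of at least 1 were kept, which left 13942 genes, called measured genes here, of which 12064 were protein-coding. A gene was called higher or lower when its log2 ratio was at least 1 in size and its counting interval excluded 0. Genes named in the text were CYP4F11 and the other CYP4F genes, and the 12 protein-coding genes furthest up and the 12 furthest down by this rule. These were ranked by the interval bound nearest 0. Of each gene list, up to 4 members that passed the rule were named, or up to 2 members with the largest log2 ratios where none passed. Genes named outside this rule are marked as chosen after their values were seen. A member of 1 list that the rule names is not reported here.

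A set of 38 gene lists with 933 entries was fixed, with the rules above, before the data were examined. Of the entries, 899 were found by symbol, 33 by an older or newer symbol, and 1 was not found. For each of the 34 lists with at least 3 measured members, the median log2 ratio was given with an interval from order statistics over members. Its percentile was taken among 10000 random lists of the same size drawn from 20 bins of mean CPM. After a relation with GC content was seen, random lists matched in 10 bins of mean CPM by 10 bins of transcript GC content were added. A correction of the log2 ratios by lowess on GC content with a span of 0.3 was added at the same time. Percentiles below 2.5 or above 97.5 are described as outside the central 95%, as a description of these 2 libraries. Among genes that passed the size rule and list genes, those that share over 10% of their 50-base words with transcripts of another gene were marked as sharing reads. Other measured genes were not screened for this.

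Alternatives tried were total counts, DESeq2 1.42.0 size factors and upper-quartile library sizes in place of TMM, and 2 added to each count. Also tried were no filter or a mean CPM of at least 5, thresholds of 1.5-fold and 4-fold, and an interval wholly past the 2-fold line. Other alternatives were protein-coding genes alone, list means, the GC correction and leaving out genes that share reads. The calculations ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.

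The size rule was tested on simulated counts for this comparison with known folds planted. With Poisson counts it recovered 53.1% of 49 genes planted at 2-fold, 97.9% of 48 at 3-fold and 100% of 49 at 4-fold. At 1.5-fold it passed 4.08% of 49 genes. Of 13768 genes simulated without a difference, 31 passed, and with a dispersion of 0.01 the number was 63 of 13728. That dispersion was not fitted to these libraries. At a mean CPM from 1 to 3 the observed spread was wider than counting gives (SD 0.65 against 0.42), so false calls may be more frequent there. A list planted with a difference in the simulated comparison lay at percentile 99.99 and an unchanged list at 68.0, over 13925 genes. The planted difference was larger than the median of any list with at least 3 measured members, and its genes were drawn independently. Recovery of smaller differences, or of lists whose genes vary together, was not simulated.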

Results

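The transcriptome of NCI-H460 cells was compared between 1 siControl library and 1 library from cells transfected with an siRNA against CYP4F11, 24 h after transfection. CYP4F11 encodes a cytochrome P450 that hydroxylates the omega end of fatty acids and related lipids. The series concerns its depletion and the proliferation and migration of lung cancer cells. The libraries held 16207785 and 13002179 counts, siControl first. Reads were found for 23341 genes in the siControl library and 22967 in the siCYP4F11 library. Protein-coding genes took 96.1% of the counts in both. Mitochondrially encoded genes took 5.83% in siControl and 6.04% in siCYP4F11, and the 10 most counted genes took 6.90% and 7.03%. With 1 library per group, no difference reported here has a replicate check.

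CYP4F11 mRNA was lower in the siCYP4F11 library, at 972 counts against 3180 in siControl. This was 74.5 CPM against 197 CPM, a log2 ratio of -1.40 (95% counting interval -1.51 to -1.30). The level was 37.8% of the control (35.1% to 40.6%), which is 62.2% lower. The gene (ENSG00000171903) lies on the minus strand of chromosome 19 from 15912367 to 15934867 on GRCh38. Of the 4329 genes with a mean CPM of at least 50, 2 others passed the size rule, both lower, and none was higher. CYP4F3, the only other CYP4F gene with a mean CPM of at least 1, had 110 and 121 counts and a log2 ratio of 0.44 (0.06 to 0.83). CYP4F12 had 0 reads in siControl and 2 in siCYP4F11. CYP4F2, CYP4F8 and CYP4F22 had 0 reads in both libraries, below the floor of 0.185 CPM in siControl and 0.231 CPM in siCYP4F11. The upper ends of their 95% counting intervals were 0.229 CPM in siControl and 0.283 CPM in siCYP4F11. Of the other CYP4 genes, CYP4V2 alone was measured, at a log2 ratio of -0.19 (-0.46 to 0.09).

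Among well-expressed genes, the lower side held most of the large differences. FADS2, a desaturase of polyunsaturated fatty acid synthesis, had 693 counts against 2177, a log2 ratio of -1.34 (-1.47 to -1.22). MGAT5, a glycosyltransferase that branches N-glycans, had 323 against 1269, at -1.67 (-1.85 to -1.49). ZNHIT1, whose product is part of a chromatin remodelling complex and which overlaps PLOD3 on the other strand, was at -1.69 (-1.91 to -1.48), and the zinc finger transcription factor CASZ1 at -1.70 (-2.01 to -1.40). SHISAL1 was at -1.78 (-2.15 to -1.44) and IGFN1 at -1.50 (-1.82 to -1.20). INSIG1, which holds the sterol sensor of SREBP processing in the endoplasmic reticulum, was the only gene with a mean CPM of at least 10 on the higher side. It had 446 counts against 246, a log2 ratio of 1.16 (0.94 to 1.40).

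By the size rule, 98 genes were higher and 175 lower in the siCYP4F11 library, of 13942 measured, so 35.9% of them were higher. Of the 273, 222 had a mean CPM below 3, and counting error alone would give 33 passing genes, all below that level. The spread between the libraries was wider than counting error there, so 33 is no estimate of the false calls. At a mean CPM of at least 10 the numbers were 1 higher and 12 lower. Besides the genes above, these 12 hold VGF, a secreted neuropeptide precursor, at -1.17 (-1.39 to -0.96), which was named after its value was seen. They also hold U2AF1, RPL41P1, RPS3AP26 and RN7SL5P, also named after their values were seen, which share reads with near-identical copies. U2AF1 was at -1.30, and with its copy U2AF1L5 added the pair was at -0.95 (-1.23 to -0.69). Of the 273 genes, 68 share over 10% of their 50-base words with another gene, and the share over all measured genes was not computed. The plot of log2 ratio against expression level shows how the ratios narrow as expression rises.

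**Figure D1:**
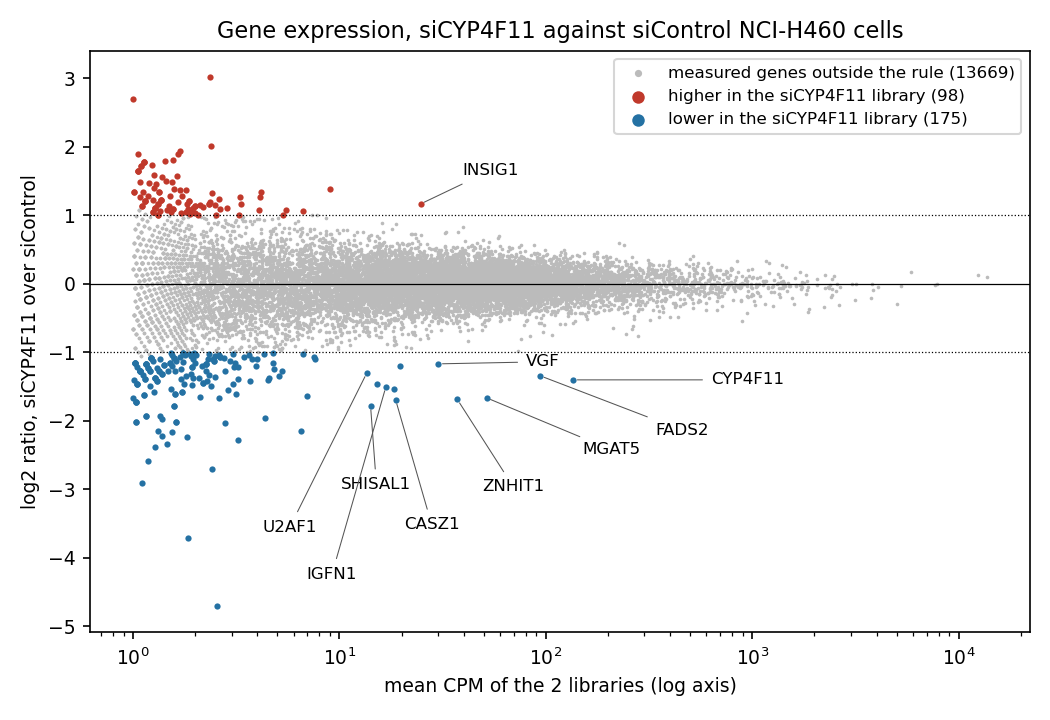
Each point is 1 of 13942 genes, with mean CPM of the 2 libraries on a log axis and the log2 ratio of siCYP4F11 over siControl on the other axis; dotted lines mark log2 ratios of 1 and -1. Red points (98) and blue points (175) passed the size rule, and CYP4F11 and FADS2 are the lower genes furthest to the right.

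Further protein-coding genes on the lower side had low counts. CACNA1H, a T-type calcium channel, had 8 counts against 68 (log2 ratio -2.70, -4.05 to -1.72). CAMK2N2, an inhibitor of a calcium-dependent kinase, had 4 against 33 (-2.59, -4.70 to -1.25). TMSB15B had 14 against 87 (-2.29, -3.26 to -1.51). It shared 8.18% of its 50-base words with other genes, mainly a second entry of the same symbol, whose counts are not given here. MAGED4B and BOLA2B each share all their 50-base words with a copy. MAGED4B with MAGED4 added was at -1.40 (-2.16 to -0.73), and BOLA2B with BOLA2 at -1.64 (-2.16 to -1.17).

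On the higher side most named genes had low counts. DUSP28 had 118 against 70 (log2 ratio 1.06, 0.62 to 1.51), PARM1 76 against 39 (1.26, 0.69 to 1.86) and TC2N 78 against 38 (1.33, 0.77 to 1.94). FAM181B was at 1.81 (0.82 to 2.98), C19orf73 at 1.73 (0.63 to 3.06) and C6orf163 at 1.77 (0.62 to 3.20). RNFT1 was at 1.38 (0.99 to 1.79), CLTRN at 1.57 (0.64 to 2.66), DET1 at 1.93 (0.97 to 3.10) and CFHR3 at 2.01 (1.19 to 2.98), and these share over 10% of their 50-base words with another gene. RGPD6 was at 3.01, but with its copy RGPD5 added the pair was at 0.58 (0.08 to 1.09).

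The spread between the libraries exceeded counting error at every expression level. The SD of log2 ratios was 0.65 for genes with a mean CPM from 1 to 3, where counting alone gives 0.42. It was 0.18 at a mean CPM of at least 100, where counting alone gives 0.041. Among genes with a mean CPM of at least 10, log2 ratios decreased with transcript GC content, with a Spearman correlation of -0.42 across 9590 genes, which are not independent replicates. The median was 0.15 in the tenth of genes with the lowest GC content and -0.13 in the tenth with the highest. Count-weighted GC content was 49.1% in siControl and 48.6% in siCYP4F11. Because of this relation, list percentiles are given against random lists matched on expression, followed by those matched on expression and GC content.

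**Figure D2:**
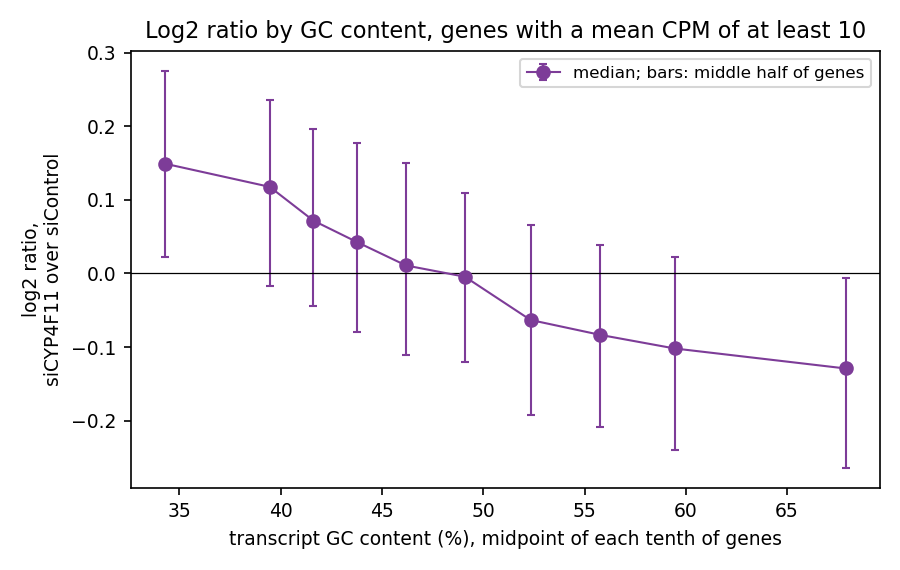
Points are median log2 ratios of siCYP4F11 over siControl in 10 equal groups of genes by transcript GC content (%), with a mean CPM of at least 10, and bars span the 25th to 75th percentile of genes. The median goes from 0.15 at the lowest GC content to -0.13 at the highest.

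Of 34 gene lists with at least 3 measured members, 9 lay outside the central 95% of random lists matched on expression, 7 above and 2 below. With GC content matched as well, 11 lay outside, 9 above and 2 below, where lists of independently drawn genes would give 1.7. Genes of a list may vary together between any 2 cultures, and lists share members. The number to expect from unrelated culture differences is therefore unknown. The differences were small for single genes, and 6 of the 730 list genes measured passed the size rule.

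Genes activated by the tumour suppressor p53 were mostly higher in the siCYP4F11 library. The median of 30 members was 0.27 (interval over members 0.13 to 0.37), with 22 above 0 and 8 below, at percentile 100 under both matchings. BTG2, an antiproliferative gene, was at 0.71 (0.49 to 0.93), while TP53I3 was at -0.89 (-1.15 to -0.63). Of members named after their values were seen, the cell cycle inhibitor CDKN1A was at 0.42 (0.31 to 0.54) and MDM2, the ubiquitin ligase for p53, at -0.03 (-0.14 to 0.07). None of the 30 passed the size rule. Apoptosis regulators had a median of 0.16 over 24 members (-0.04 to 0.20), at percentiles 99.9 and 99.8, and at 90.2 after the GC correction. FAS was at 0.64 and APAF1 at 0.50.

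Sterol genes were higher as a group, while fatty acid genes were mixed. The cholesterol synthesis list had a median of 0.23 over 23 members (-0.01 to 0.41), with 16 above 0, at percentile 100 under both matchings. MSMO1, a sterol oxidase, was at 0.89 (0.62 to 1.17). Fatty acid synthesis had a median of 0.14 over 17 members (-0.14 to 0.31), at percentiles 99.5 and 99.7. In this list INSIG1 was higher and FADS2 lower by the size rule. SCD, another desaturase named after its value was seen, had 9493 against 17162 counts, a log2 ratio of -0.55 (-0.58 to -0.51). Fatty acid oxidation and PPAR targets had a median of -0.01 over 24 members (percentiles 43.1 and 53.5), with TXNIP at -0.49 and PDK4 at 0.43.

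NRF2 targets, genes of the oxidative stress response, had a median of 0.14 over 34 members (0.08 to 0.22), with 25 above 0, at percentile 100 under both matchings. GCLC, the catalytic subunit of glutathione synthesis, was at 0.44 (0.33 to 0.55), and CYP4F3 is a member of the list too. Nuclear-encoded respiratory chain genes had a median of 0.11 over 36 members (0.05 to 0.16), with 30 above 0, at percentiles 99.9 and 99.97. NDUFB5 was at 0.52 and NDUFA4 at 0.33. Xenobiotic metabolism genes had a median of 0.17 over 14 members (-0.15 to 0.32), at percentiles 98.9 and 97.9, and at 91.6 after the GC correction. CYP39A1 was at 0.57 and AHRR at -0.55. ATF4 and amino acid response genes had a median of 0.07 over 29 members (-0.008 to 0.14), at percentiles 97.485 and 99.9, with NUPR1 at 0.48 and GDF15 at 0.41. Unfolded protein response genes had a median of 0.09 over 21 members (0.005 to 0.17), at percentiles 97.4 and 98.2, with DNAJB9 at 0.55 and DNAJC3 at 0.48.

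The YAP/TEAD target list and the list of MYC targets and ribosome biogenesis genes were lower. YAP/TEAD targets, which respond to cell contact and the cytoskeleton, had a median of -0.15 over 22 members (-0.38 to -0.04), with 19 below 0, at percentiles 0.31 and 0.54. AMOTL2 was at -0.47 (-0.56 to -0.37) and CYR61, a secreted matrix protein, at -0.46 (-0.57 to -0.35). MYC targets and ribosome biogenesis genes had a median of -0.11 over 27 members (-0.20 to -0.02), with 21 below 0, at percentiles 0.43 and 1.46. BOP1 was at -0.46 and MYBBP1A at -0.39. Ribosomal proteins had a median of -0.03 over 55 members (percentiles 33.3 and 60.5), with RPL3 at -0.19 and RPS9 at -0.18, and 0.03 after the GC correction.

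Lists of cell cycle phases, histones and immediate early genes lay inside the central 95%. G1/S genes had a median of 0.02 over 35 members (percentiles 59.7 and 86.8), with CCNE2, a G1/S cyclin, at 0.75 and UHRF1 at -0.44. G2/M genes had a median of 0.05 over 36 members (91.3 and 66.3), with CDK1, the mitotic kinase, at 0.56 (0.49 to 0.63) and CCNA2 at 0.45. Replication-dependent histones had a median of 0.00 over 14 members (59.0 and 60.4), with HIST1H4H at 0.87 and HIST1H2AI at -0.43. Immediate early and ERK feedback genes had a median of -0.06 over 25 members (-0.23 to -0.009), with 19 below 0, at percentiles 9.06 and 40.0. EPHA4 was at -0.40 and FOS at -0.35.

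Lists of migration, mesenchymal, epithelial and TGF-beta genes also lay inside it. Migration, adhesion and proteolysis genes had a median of -0.07 over 34 members (percentiles 5.54 and 12.8), with TIMP3 at -0.93 and PLAU at -0.46. Mesenchymal and EMT genes had a median of -0.04 over 20 members (36.1 and 57.2), and LOX, which crosslinks collagen, was lower by the size rule with 10 against 39 counts, at -1.61 (-2.82 to -0.63). Epithelial genes had a median of -0.03 over 12 members (39.3 and 69.5), with MUC1 at -0.99 and CLDN7 at 0.53. TGF-beta targets had a median of -0.06 over 19 members (23.9 and 39.9), with TGFB1 at -0.73 and PMEPA1 at -0.63.

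The next 7 lists lay inside the central 95% under both matchings too. Eicosanoid metabolism had a median of 0.10 over 21 members (percentiles 95.4 and 96.0), with PTGR2 at 0.92 and PTGS1 at 0.88 (-0.08 to 1.90, 24 against 16 counts). Vitamin K and vitamin E handling had 0.12 over 7 (89.7 and 93.4), with GGCX at -0.24 and VKORC1 at 0.20. Heat shock genes had -0.02 over 17 (37.5 and 28.9), with CRYAB at -0.47 and HSPE1 at 0.38. Interferon-stimulated genes had a median of 0.04 and a mean of -0.07 over 28 (76.5 and 74.3), and IFIT1, an interferon-induced antiviral gene, was lower with 6 against 30 counts, at -1.92 (-3.57 to -0.73). NF-kB targets and inflammatory genes had 0.00 over 22 (51.7 and 49.98), with IL1A at 0.72 and ICAM1 at 0.47. Ferroptosis and glutathione genes had 0.04 over 20 (84.5 and 91.4), with CBS, which shares reads with CBSL, at -0.50 and GCLC as above. RNA interference machinery had 0.08 over 13 (85.0 and 82.1), with AGO1 at 0.39 and TARBP2 at 0.25.

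Of the metabolic and organelle lists not yet given, hypoxia genes had a median of -0.04 over 25 members (percentiles 20.4 and 22.1), with EGLN3 at 0.54 and MXI1 at -0.54. Glycolysis genes had -0.06 over 20 (14.3 and 53.8), with the glucose transporter SLC2A1 at -0.48 and HK2 at -0.40. Mitochondrially encoded genes had 0.00 over 13 (64.4 and 22.4), with MT-ATP8 at -0.34 and MT-ND3 at 0.21. Autophagy and lysosome genes had 0.04 over 24 (79.8 and 93.5), with NPC2 at 0.48 and ATG12 at 0.34, and lay at percentile 99.7 after the GC correction.

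Few markers of other cell types were measured. Neuroendocrine genes had a median of -0.20 over 6 members (percentiles 3.51 and 6.82), with SYP at -0.48 and SYT1 at -0.45. Fibroblast and endothelial markers had 0.26 over 5 (94.8 and 94.6, and 98.9 after the GC correction), with DCN at 0.77 and LUM at 0.59. Leukocyte markers and alveolar and airway markers had 1 measured gene each. These were CD14, higher by the size rule with 33 against 20 counts at 1.01 (0.18 to 1.91), and AGER, with 22 against 21 counts at 0.37 (-0.56 to 1.31). The CYP4F list and the list of other CYP4 genes had 2 and 1 measured genes, given above. Of the list members named, UHRF1, RPL3, RPS9, HSPE1, VKORC1, PTGR2, CLDN7 and HIST1H2AI also share over 10% of their 50-base words with another gene, so their values are less certain. Counting intervals included 0 for AHRR, CLDN7, CRYAB, FOS, HIST1H2AI, ICAM1, PTGS1, SYP and VKORC1, so the direction of these genes is not settled.

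**Figure D3:**
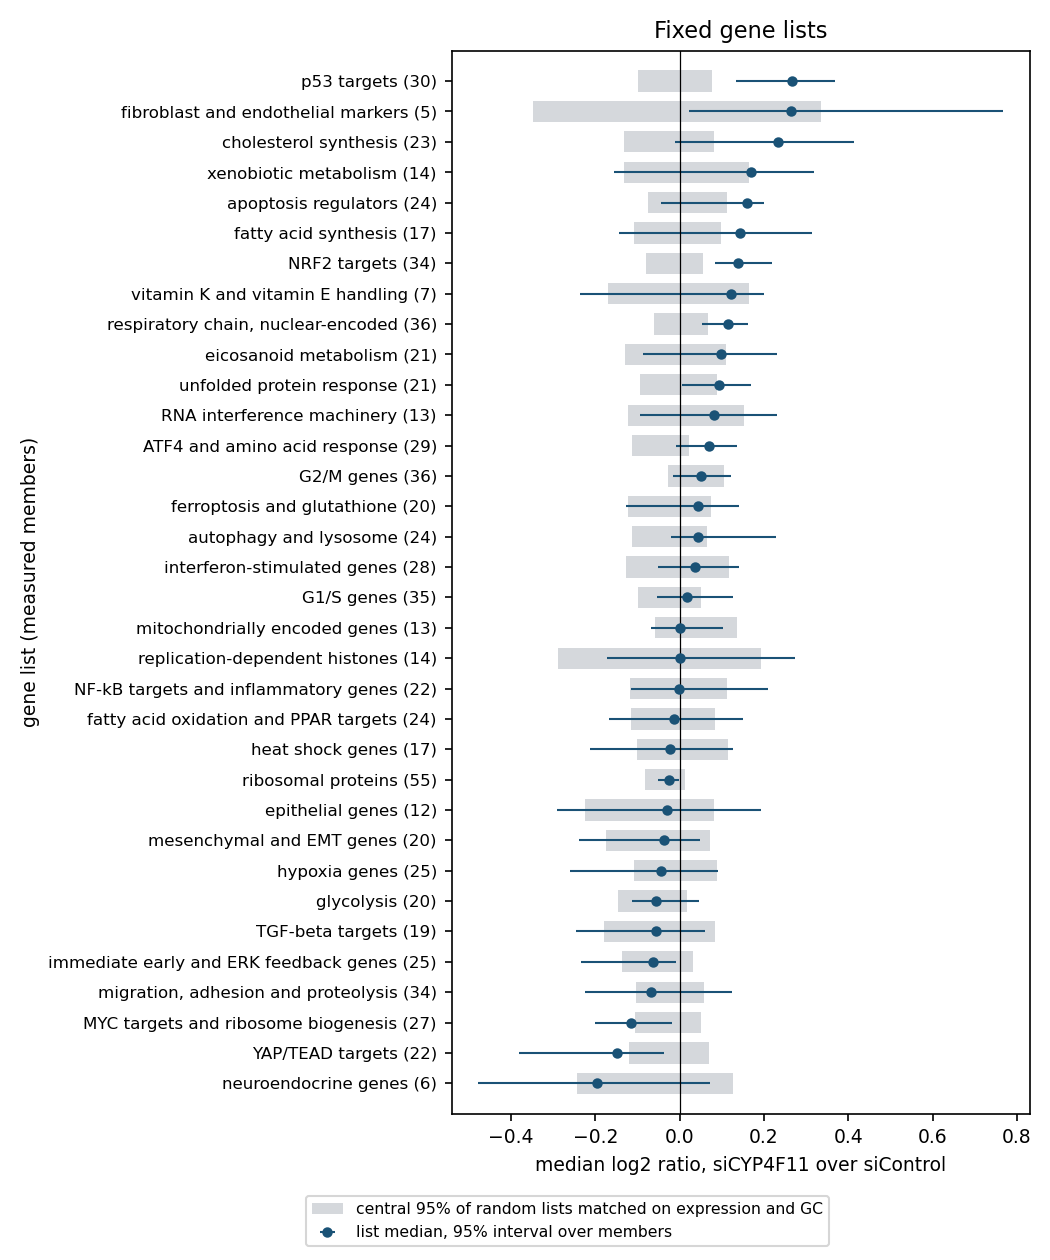
Points are the median log2 ratio of siCYP4F11 over siControl for each of 34 gene lists, bars are 95% intervals over members, and grey bands hold the central 95% of random lists matched on expression and GC content; measured members are in parentheses. The p53 list (0.27), the cholesterol list (0.23) and the NRF2 list (0.14) lie above their bands, and the YAP/TEAD list (-0.15) lies below.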

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

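The GC correction, GC-matched lists and leaving out genes that share reads were chosen after the data were seen. CYP4F11 stayed lower under every alternative run, from -1.40 with 2 added to each count to -1.35 with the GC correction. The counts of genes depended on the filter and the threshold. With no filter on low counts, 345 genes were higher and 476 lower, and with a mean CPM of at least 5 there were 5 and 19. A 1.5-fold threshold gave 284 and 479, a 4-fold threshold 3 and 18, an interval wholly past the 2-fold line 3 and 24, and protein-coding genes alone 50 and 103. These follow from testing more or fewer genes or from a laxer or stricter rule. The share of higher genes went from 35.9% to 20.8% at a mean CPM of at least 5, 14.3% at 4-fold and 11.1% with the strict interval. Other scalings gave 100 to 101 higher and 167 to 175 lower genes. The GC correction gave 100 and 167, of which 89 and 153 were among the original calls. Of 34 list medians, those that left their 95% interval over members were the interferon-stimulated list by its mean (-0.0731) and the ribosomal protein list with the GC correction (0.0312); the cause was not tested. These 2 changed sign, as did 6 more within their intervals, such as glycolysis at 0.02 with the GC correction, but 0 of the 9 outside the central 95% did. Of 89 named genes, 11 moved beyond their counting interval with the GC correction and none with another scaling. No result changed direction among those called. Depth limits genes below a mean CPM of 3 most, where counting alone gives a log2 SD of 0.42. No paired analysis was possible because each group had 1 library.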

Other observations

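All tests in this part were chosen after the results they concern had been seen, except the test of the 4 lists together without seed-matched genes, which was set down before its result. Of 451 measured genes that the deposited table assigns to the zf-C2H2 zinc finger family, 306 had a log2 ratio below 0, with a median of -0.12 (-0.14 to -0.08), at percentile 0 under both matchings. Smaller families had medians as low with wider intervals, RHD at -0.16 (-0.29 to 0.02), THR-like at -0.16 (-0.30 to 0.05) and ARID at -0.13 (-0.28 to 0.09), at GC-matched percentiles of 6.19, 5.49 and 3.57. HMG was at -0.08 (-0.29 to -0.001), at a GC-matched percentile of 3.54. Of the 14 families, 12 had medians below 0, but the median of all measured genes was also below 0, at -0.005. ETS (-0.007), THAP (-0.005) and Homeobox (-0.010) lay near it. The count of signs therefore does not show whether lower values were particular to zf-C2H2. With GC matched, MYB (-0.09 over 20 genes, percentile 1.27) also lay below the central 95%, and TF_bZIP (0.05 over 38, percentile 98.1) above it. The zf-C2H2 median was -0.11 for the 174 on chromosome 19, -0.12 for the 277 elsewhere, and -0.11 for the 233 without the 6-base word GCTGAT in the transcript, which lay at a GC-matched percentile of 0. The 692 other genes of chromosome 19 were also at -0.12, but at a GC-matched percentile of 8.02. The family was looked at because a word in zinc finger coding sequence led a scan of coding regions on these log2 ratios, so its percentile restates that observation and does not test it, and 20 families and subsets were computed.

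VGF and ZNHIT1, both lower by the size rule, are neighbours on chromosome 7. VGF lies from 101162509 to 101165593 with a log2 ratio of -1.17, and ZNHIT1 from 101217668 to 101224190 with -1.69. PLOD3, between them and overlapping ZNHIT1 on the other strand, was at -0.14 (-0.21 to -0.07), and AP1S1, beside VGF, was at 0.16 (0.07 to 0.26).

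Genes with the word AGCTGATA in the 3′ UTR were lower in the siCYP4F11 library, after a fit on expression, length and GC content. The difference was small, with a median of -0.089 (-0.121 to -0.041) over 290 genes, 63.1% of them below 0, and -0.063 before the fit. The word was chosen as the lowest of 59770 words of 8 bases in these same genes. This median, its interval and the medians of its shorter matches are therefore not independent of that choice and may overstate the difference. Genes with GCTGATA alone were at -0.036, with AGCTGAT short of the 8-base word at -0.017, with GCTGAT alone at 0.003 and without a match at 0.014. The standardised shift below is a word's mean difference from all genes in standard errors, not a log2 ratio. Among 16303 words of 7 bases in 10131 genes, GCTGATA (standardised shift -9.72) and AGCTGAT (-9.53) led, the next was at -4.94, and 0 of 100 shuffles of the ratios over genes gave as large a shift, which argues against chance among the 7-base words (6-base and 8-base words and coding regions were scanned too). Chosen in 5065 genes, where its standardised shift was -8.42, GCTGATA was at -5.26 in the other 5066. In those 5066 genes 1 of 629 words of the same bases was as low, the overlapping AGCTGAT, which argues against base composition. A scan without the size-rule genes led to the same 8-base word, and 24 of 97 lower genes had a 7-base or 8-base match against 13.2 in sets matched on 3′ UTR length (percentile 99.92), with 8 of 50 higher genes at percentile 49.6, but of the named genes 3 of 11 furthest down besides CYP4F11 (MGAT5, SHISAL1 and FADS2) and 3 of 12 furthest up (PARM1, TC2N and RGPD6) had such a match. A candidate explanation is pairing with the seed of the siRNA, since the word also lies in exon 12 of CYP4F11, in coding sequence at chromosome 19 from 15913792 to 15913799, but 4.71% of the 8-base words do so, the siRNA sequence is not given, and the fit made first did not set 3′ UTR matches apart from matches elsewhere (median difference -0.0069, -0.0561 to 0.0446), while a second fit with the rest of the transcript, made after that result, gave -0.0623 (-0.105 to -0.0025).

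Of the 34 lists, 9 lay outside the central 95% of random lists matched on expression. GC content bias was argued against as the whole cause for the 7 of these that stayed outside both with GC-matched lists and with the GC correction, among them p53 targets and YAP/TEAD targets, and it stays open for the other 2, apoptosis regulators and xenobiotic metabolism, which came inside with the correction. Loss of seed-matched genes from the rest of the transcriptome was tested on p53 targets, NRF2 targets, cholesterol synthesis and the respiratory chain, picked after their percentiles were seen, and among genes without the 6-base match their lowest percentile was 94.45, that of the respiratory chain, below the limit set beforehand, while the other 3 stayed above it. Lowering of genes with a 3′ UTR match, as the whole cause, was argued against for p53 targets. Without such genes the p53 list lay at percentile 100, with a median of 0.264 (0.133 to 0.433) against random lists up to 0.129. NRF2 targets (0.12 of 0.14 kept, percentile 99.89) and cholesterol synthesis (0.16 of 0.23, percentile 99.04) had intervals over members that reach into the random range. The cause therefore stays open for these 2 lists and for the respiratory chain. Matches outside the 3′ UTR and later effects of a lowered seed-matched gene were not covered. Other effects of the siRNA on genes besides CYP4F11 thus stay open for p53 targets too. A difference between single cultures unrelated to CYP4F11 cannot be told apart from an effect of the knockdown, since there was 1 control library, and an effect of CYP4F11 itself is equally untested.

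GC-rich genes were lower across the transcriptome. GC-dependent library preparation or amplification could give this, and the correlation among 341 non-coding genes and pseudogenes was -0.22, of the same sign as the -0.43 among protein-coding genes. With 1 library per group, library preparation cannot be told apart from a difference between the cells, which was not tested.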
